A study of Mus musculus with 11 samples.

How the data were processed

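RNA from mucosal scrapings of the mouse colon was measured on single-colour expression arrays, 1 array per mouse, in 5 mice fed a control diet and 6 mice fed the same diet with inulin. Groups were taken from the labels of each sample. Per the labels' protocols the animals were separate male C57BL/6J mice, divided over the diets by body weight, so the spread within a group is the spread between mice. The labels give no cage, batch or scan date, so none was tested. Whether mice of a diet shared a cage, or cage differed with diet, is not known. The same protocols describe RNA with an integrity number above 8.0, amplified and biotin-labelled with a whole-transcript kit.

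The authors deposited 1 table of log2 array values, normalised with the robust multi-array average (RMA) per the submitters' processing notes. RMA corrects the background of each array, makes the distributions of the arrays alike and summarises the probes of a probe set on a log2 scale. The version of RMA, the probe set definition and the genome build are not given in the sources used here, and no coordinates are printed. The log2 scale was checked on the values, which ran from 1.46 to 13.7. Scanner intensities were not used here, so no value could be set against a measured background, and array values near the lower quartile of all probe sets carry little signal. Making the arrays alike also removes any shift shared by most genes.

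The table holds 35556 probe sets. The platform annotation, whose symbols can be older than current ones, gave 1 gene symbol to 21218 of them, several symbols to 1881, and did not list 12457. The Entrez number of 21185 of the probe sets with 1 symbol was found in the RefSeq gene table of the mouse assembly GRCm38.p6, and 0 had another symbol there. Probe sets with several symbols or none were left out of the tests of genes. Of the 18820 remaining genes, 1386 had more than 1 probe set, and the probe set with the highest mean over the 11 arrays was used.

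Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 values (lmFit and eBayes, inulin minus control, all 11 mice, no covariate), and p-values were adjusted over 18820 genes by the Benjamini-Hochberg method, with a threshold of 0.05. A fold is 2 raised to the difference of the log2 means, and errors beside differences are limma's standard errors. For Angptl4 and the other genes of the study's question, a two-sided exact permutation test over all 462 divisions of the 11 mice into 5 and 6 was added, whose smallest possible p is 0.0022. Lists of genes were tested with camera from limma, at its preset correlation between genes of 0.01, adjusted over 44 lists. Beside each list the p with a correlation estimated from the data is given, and members are counted past the threshold over all genes and adjusted over the list alone. Camera compares a list with all other genes, whereas fry, run as an alternative, asks whether the genes of a list move one way on balance.

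The groups, the tests, the 44 lists with 947 genes, of which 850 were measured, and most alternatives were fixed before the data were examined. Named genes follow a rule fixed at the same time. It took the 14 genes of the study's question, up to 12 rises and 12 falls past the threshold leaving out predicted genes and small RNAs, up to 4 members past the threshold in each called list or otherwise the 2 with the smallest p, and the leading 2 members of each cell type list. Further members named below were chosen after their values were seen. These are the members past the threshold over their list alone, along with Cd36, Aqp7, Acot2, Ehhadh, Duox2 and Hoxb13. Of the 14 genes of the question, 1 is not reported here.

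The steps were tested on simulated data for inulin against control with the real spreads of the 18820 genes. The noise was normal, independent between genes and equally wide in both diets. It holds no outlying mouse, so the real arrays may allow less than the shares given here. Of 50 genes changed by 0.5 on the log2 scale, 76% were recovered. Of 50 genes each changed by 1, 1.5 and 2, 98%, 100% and 100% were recovered. With 200 genes changed at once the adjustment was also milder than in the real data, where 17 genes passed. The share for a change of 0.5 may therefore be too high for the real data. The 11 arrays limit the precision, and no depth applies to an array.

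Alternatives were a variance prior that follows intensity, a robust prior, array weights, leaving out probe sets below the 40th percentile of mean value, quantile normalisation, centring each array on its median, the mean of a gene's probe sets, the replicate number as a block, leaving out each mouse in turn, an unmoderated test allowing unequal variances, thresholds of 0.01 and 0.1, a minimum of 1.2-fold, all probe sets, camera on ranks or with an estimated correlation, and fry. Chosen after seeing the data were covariates for fat and pancreas markers (17 and 13 genes found in no other list), a covariate for Hoxb13 and Hoxa13, leaving out inulin mice 3, 4 and 5, and exact permutation tests of list means.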

Results

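Colon mucosa was profiled in male C57BL/6J mice of 12 weeks after 10 days on 1 of the diets, which followed 2 weeks of adaptation. Control mice (n = 5) ate a low-fat diet, and inulin mice (n = 6) ate the same diet with 10% by weight of corn starch replaced by inulin, a fructan fibre that gut bacteria ferment to short-chain fatty acids. The labels differ on the last hours. The treatment protocol has the mice fed 1 g of diet after an overnight fast and killed 4 h later, whereas the design text has colon taken after the fast. The 11 arrays had medians between 5.38 and 5.46, lower quartiles between 3.72 and 3.79 and upper quartiles between 7.71 and 7.75, and correlations between arrays over all genes ran from 0.988 to 0.998. The first principal component held 30.9% of the variance and placed inulin mouse 5 at 37.0, far from the other mice, which lay between -12.3 and 13.5.

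The comparison of inulin with control asks which colonic genes respond to a fermentable fibre. Reg3g and Reg3b, secreted lectins that act on bacteria at the mucosal surface, rose most among the genes past the threshold. Reg3g went from a log2 value of 8.56 ± 0.68 (SD, n = 5) to 11.39 ± 0.47 (SD, n = 6), a 7.10-fold rise, and Reg3b from 9.95 ± 0.85 to 12.26 ± 0.37, a 4.93-fold rise. S100g, the calcium-binding protein calbindin-D9k of absorptive cells, fell by 1.99 on the log2 scale, from 8.77 ± 0.45 to 6.78 ± 0.35. Itln1, an intestinal lectin that binds microbial sugars, fell by 2.21, from 6.47 ± 0.21 to 4.26 ± 0.88, near the lower quartile of the arrays. In limma the adjusted p was 0.0024 for Reg3g, 0.020 for Reg3b, 0.0024 for S100g and 0.032 for Itln1.

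The other rises were smaller. Mal, a membrane protein of apical transport, rose 2.76-fold (log2 difference 1.46 ± 0.15 SE, adjusted p 0.0024). Lpo, a secreted peroxidase, rose 1.84-fold (0.88 ± 0.14 SE, adjusted p 0.043). Cck, the satiety hormone of enteroendocrine cells, rose 1.53-fold (0.61 ± 0.091 SE, adjusted p 0.025). Fa2h, which hydroxylates fatty acids of sphingolipids, rose 1.40-fold (0.49 ± 0.053 SE, adjusted p 0.0025). Ttyh1, Cwh43, Cspg4 and Prss30 rose 1.43-fold, 1.38-fold, 1.38-fold and 1.36-fold. Among the falls, Gnat3, the taste G protein gustducin found in tuft cells, fell by 0.73 on the log2 scale (SE 0.088, adjusted p 0.0069). The amino acid transporter gene Slc6a20a fell by 0.60, the integrin gene Itgb8 by 0.57, Nrbp2 by 0.50 and St18 by 0.46, with adjusted p between 0.022 and 0.026.

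In all, 17 of 18820 genes passed, 10 higher and 7 lower. With an unmoderated test allowing unequal variances 0 passed. With each array centred on its median 62 passed, 44 higher and 18 lower, but centring also moved the median difference of all genes from 0.0039 to 0.030, towards rises. At an unadjusted p under 0.05, 2547 genes passed. The count depended on single mice: it was 7 without control 1, 7 without control 2, 10 without control 3, 38 without control 4, 8 without control 5, 9 without inulin 1, 10 without inulin 2, 11 without inulin 3, 98 without inulin 5 and 50 without inulin 6. Reg3g, Mal, S100g, Fa2h, Gnat3, Ttyh1 and Cspg4 passed whichever mouse was left out, whereas Itln1 passed in 2 of the 11 fits, and its second probe set, not used, differed by -0.54.

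**Figure D1:**
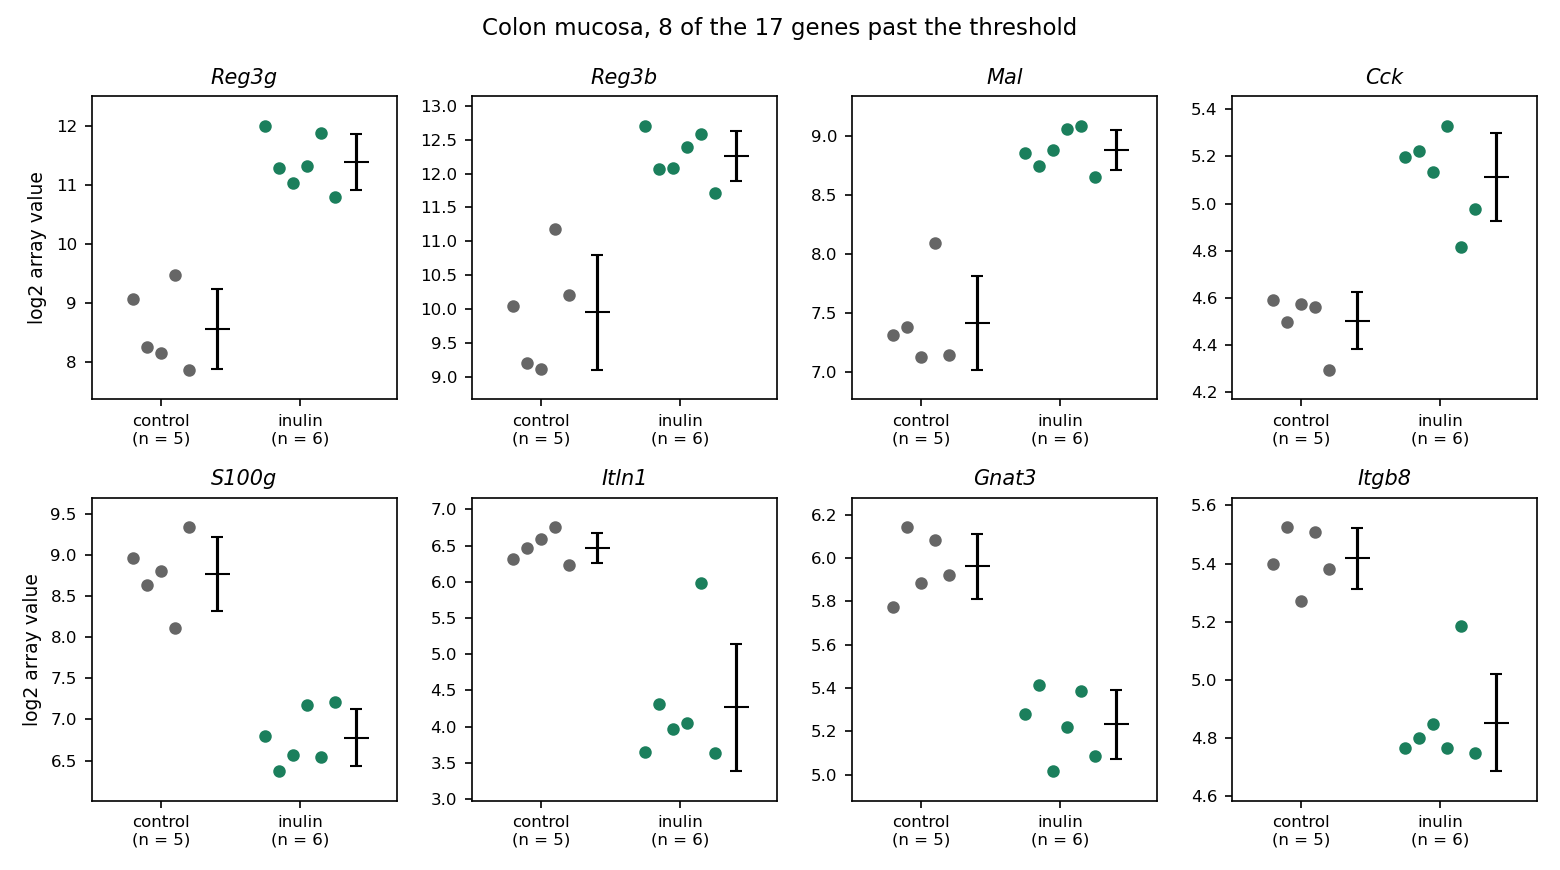
Log2 array value (vertical axis) per mouse for 8 of the 17 genes, control (grey, n = 5) and inulin (green, n = 6), with the mean and SD as the black bar beside each group. Reg3g, Reg3b, Mal and Cck lie higher in every inulin mouse than in any control, and S100g, Itln1, Gnat3 and Itgb8 lower, with inulin 5 at 5.98 for Itln1 nearest to the controls.

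The series title names Angptl4, the secreted inhibitor of lipoprotein lipase, and its induction by short-chain fatty acids through PPARγ. Angptl4 was at 6.60 ± 0.15 (SD, n = 5) in control and 6.93 ± 0.91 (SD, n = 6) in inulin colon, a 1.26-fold difference with a 95% interval from 0.743 to 2.14, and it did not pass the test (limma adjusted p 0.73). The exact permutation p was 0.43 (two-sided), and 0.84 after adjustment over the 13 measured genes of the question. Inulin mice 1 and 2 had Angptl4 at 8.11 and 8.02, above every control (6.44 to 6.78), while inulin 3 to 6 were at 6.11, 6.75, 6.59 and 6.04. The Angptl4 difference was 0.33, and it was 0.02 with Hoxb13 and Hoxa13 as a covariate, 0.60 with fat and pancreas covariates, 0.79 without inulin 3, 4 and 5, and 0.10 to 0.51 leaving out each mouse, never past the threshold. Pdk4, the kinase that restrains pyruvate oxidation, had the same mice on top, 10.20 and 10.02 against 8.05 to 8.87 in the other inulin mice and 8.32 to 8.79 in control.

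None of the 13 measured genes passed in limma, over all genes or adjusted over the list alone, where the smallest adjusted p was 0.757, and 0 had an unadjusted p under 0.05. Pparg, the receptor named in the title, differed by 0.11 ± 0.074 (SE), Ppara by -0.11 ± 0.17 and Ppard by -0.05 ± 0.071. The lipid droplet gene Plin2 differed by 0.13 and the fatty acid importer of mitochondria Cpt1a by 0.02. The butyrate transporters Slc16a1 and Slc5a8 differed by 0.02 and 0.04, the fatty acid receptors Ffar2 and Ffar3 by -0.22 and -0.04, and the chloride exchanger Slc26a3 by -0.04. Hcar2, a receptor for butyrate, lay below the lower quartile of the arrays at 3.42 and 3.44, so the arrays could hardly show a change in it.

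**Figure D2:**
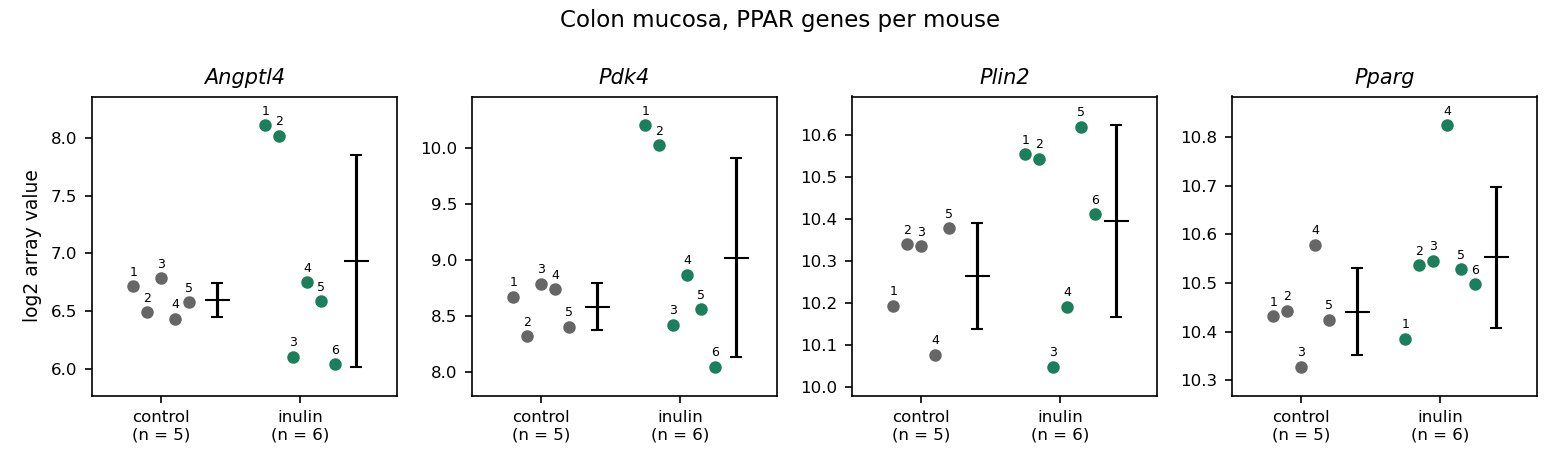
Log2 array value (vertical axis) per mouse, numbered, for Angptl4, Pdk4, Plin2 and Pparg in control (grey, n = 5) and inulin (green, n = 6), with mean and SD as black bars. Inulin mice 1 and 2 stand apart for Angptl4 (8.11 and 8.02) and Pdk4 (10.20 and 10.02).

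PPAR target genes as a list rose (camera adjusted p 0.00024; adjusted p = 0.51 with an estimated correlation). Of 36 measured members 30 were higher under inulin, with a mean difference of 0.25 and a median of 0.11. Over all genes 0 members passed, and 2 rose adjusted over the list alone: Fabp2, a fatty acid carrier of enterocytes (1.37-fold), and Cidec, a lipid droplet protein of fat cells (2.56-fold). In 18 of the 36 members (50%) inulin mice 1 and 2 held the highest values, against 459 of all 18820 genes (2.44%). The fatty acid translocase Cd36 and the glycerol channel Aqp7, both abundant in fat tissue, had differences of 1.89 ± 0.70 (SE) and 1.34 ± 0.47 (SE), and adipocyte markers were themselves higher in inulin colon. With Hoxb13 and Hoxa13 as a covariate the list did not pass (mean difference 0.11, adjusted p 0.15).

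Tuft and deep crypt secretory cell markers fell and colonocyte markers rose. For tuft cells the camera adjusted p was 6.1e-10 (adjusted p = 0.32 with an estimated correlation), their mean went from 6.26 ± 0.11 to 5.96 ± 0.15 (SD), and 15 of 15 members were lower. Over all genes 0 of them passed, and 9 fell adjusted over the list alone, led by the taste channel Trpm5 (-0.58 ± 0.10 SE) and the kinase Dclk1 (-0.41 ± 0.076 SE), and including the tuft cell regulator Pou2f3 (-0.29). Markers of deep crypt secretory cells, the colonic counterpart of Paneth cells, fell (adjusted p 0.00036; adjusted p = 0.32 with an estimated correlation), from a mean of 11.13 ± 0.11 to 10.61 ± 0.27. Adjusted over the list alone 5 of 8 fell: Ang4 by 1.23, Retnlb by 0.92, Reg4 by 0.86, Mptx1 by 0.77 and Spink4 by 0.31 on the log2 scale. Colonocyte markers rose (adjusted p 3.4e-05; adjusted p = 0.39 with an estimated correlation), with 17 of 21 higher, 0 past the threshold over all genes and 7 adjusted over the list alone, among them Prap1 (2.28-fold), Dhrs9 (1.69-fold) and Tmigd1 (1.59-fold).

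Stem and progenitor markers fell (adjusted p 0.0035; adjusted p = 0.51 with an estimated correlation), with 16 of 19 lower and 4 past the threshold adjusted over the list alone: the Wnt target Ascl2 (-0.65 ± 0.17 SE), the receptor Ephb3 (-0.41), Cdca7 (-0.29) and Lrig1 (-0.25). Inulin 5 weighed on this fall, with a list mean of 6.84 against 7.25 to 7.35 in the other inulin mice and a control mean of 7.36. Ribosome biogenesis and Myc target genes fell (adjusted p 5.2e-07; adjusted p = 0.39 with an estimated correlation), 23 of 25 lower, with Myc itself at -0.41 ± 0.087 (SE) the only member past the threshold over the list alone. Cell cycle genes fell by less (mean difference -0.07, adjusted p 0.036; adjusted p = 0.72 with an estimated correlation), with 23 of 35 lower and E2f1 (-0.27) and Uhrf1 (-0.18) leading. With fat and pancreas markers as covariates the stem, ribosome and colonocyte lists no longer passed (adjusted p 0.55, 0.33 and 0.071), and the cell cycle mean turned to 0.04. Cell cycle genes also did not pass without inulin 3, 4 and 5 or with the Hox covariate (adjusted p 0.16 and 0.58). Over all genes 0 members of the stem, ribosome and cell cycle lists passed.

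Energy metabolism lists rose by small amounts. Oxidative phosphorylation genes were higher in 31 of 33 members with a mean difference of 0.09 (adjusted p 5.2e-07; adjusted p = 0.32 with an estimated correlation), led by the complex I genes Ndufb8 (0.21 ± 0.049 SE), which passed adjusted over the list alone, and Ndufs8 (0.24 ± 0.067 SE). The TCA cycle (Sdhb 0.14, Suclg2 0.18), glycolysis (Pfkl 0.19, Tpi1 0.16) and mitochondrial fatty acid oxidation (Etfa 0.21, Acads 0.20) lists rose with adjusted p of 0.019, 0.0068 and 0.011, and adjusted p = 0.51, 0.39 and 0.56 with an estimated correlation, with 0 members past the threshold over the lists alone. In the ketone body and butyrate list (adjusted p 0.025; adjusted p = 0.39 with an estimated correlation) the ketone enzyme Bdh1 rose by 0.25 and Oxct1, which uses ketone bodies, fell by 0.31, both adjusted over the list alone. Cholesterol synthesis (Fdps 0.35, Tm7sf2 0.19) rose with adjusted p 0.0096 (adjusted p = 0.58 with an estimated correlation). Fatty acid and triglyceride synthesis rose (adjusted p 0.010; adjusted p = 0.32 with an estimated correlation): adjusted over the list alone 9 of 22 members rose, among them Dgat1 (0.26 ± 0.053 SE), Mogat2 (1.40-fold) and the desaturase Scd1 (2.55-fold), and 3 fell, Elovl7, Mlxipl and Fads2. Over all genes 0 members of these 7 lists passed, and with fat and pancreas covariates glycolysis and fatty acid synthesis did not pass (adjusted p 0.36 and 0.76). Fatty acid oxidation, ketone body and fatty acid synthesis genes did not pass with the Hox covariate (adjusted p 0.20, 0.14 and 0.060), nor did cholesterol synthesis, glycolysis and fatty acid synthesis genes without inulin 3, 4 and 5 (adjusted p 0.26, 0.057 and 0.060).

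Of the stress and detoxification lists, hypoxia response rose (adjusted p 0.0016; adjusted p = 0.39 with an estimated correlation), with Ndrg1 (1.38-fold), Car9 (1.21-fold), Stc2 (1.28-fold) and Higd1a (1.31-fold) past the threshold over the list alone. Xenobiotic metabolism (adjusted p 0.013; adjusted p = 0.51 with an estimated correlation) had 5 members that rose over the list alone, led by the retinal dehydrogenase Aldh1a1 (1.47-fold) and the efflux pump Abcg2 (1.27-fold), and 1 that fell, the carboxylesterase Ces2a (-0.49). NRF2 and glutathione genes rose (adjusted p 0.025; adjusted p = 0.47 with an estimated correlation) with Mgst1 (1.38-fold) and Nqo1 (1.26-fold). Glucocorticoid response genes rose (adjusted p 0.019; adjusted p = 0.51 with an estimated correlation) with Fkbp5 (1.31-fold) past the threshold over the list alone, while Lcn2 differed by 0.25. Over all genes 0 members of these 4 lists passed. Hypoxia and xenobiotic genes did not pass with fat and pancreas covariates (adjusted p 0.68 and 0.18), and the xenobiotic mean turned to -0.04 with the Hox covariate. NRF2 genes did not pass with the Hox covariate (adjusted p 0.060), nor hypoxia genes without inulin 3, 4 and 5 (adjusted p 0.062).

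**Figure D3:**
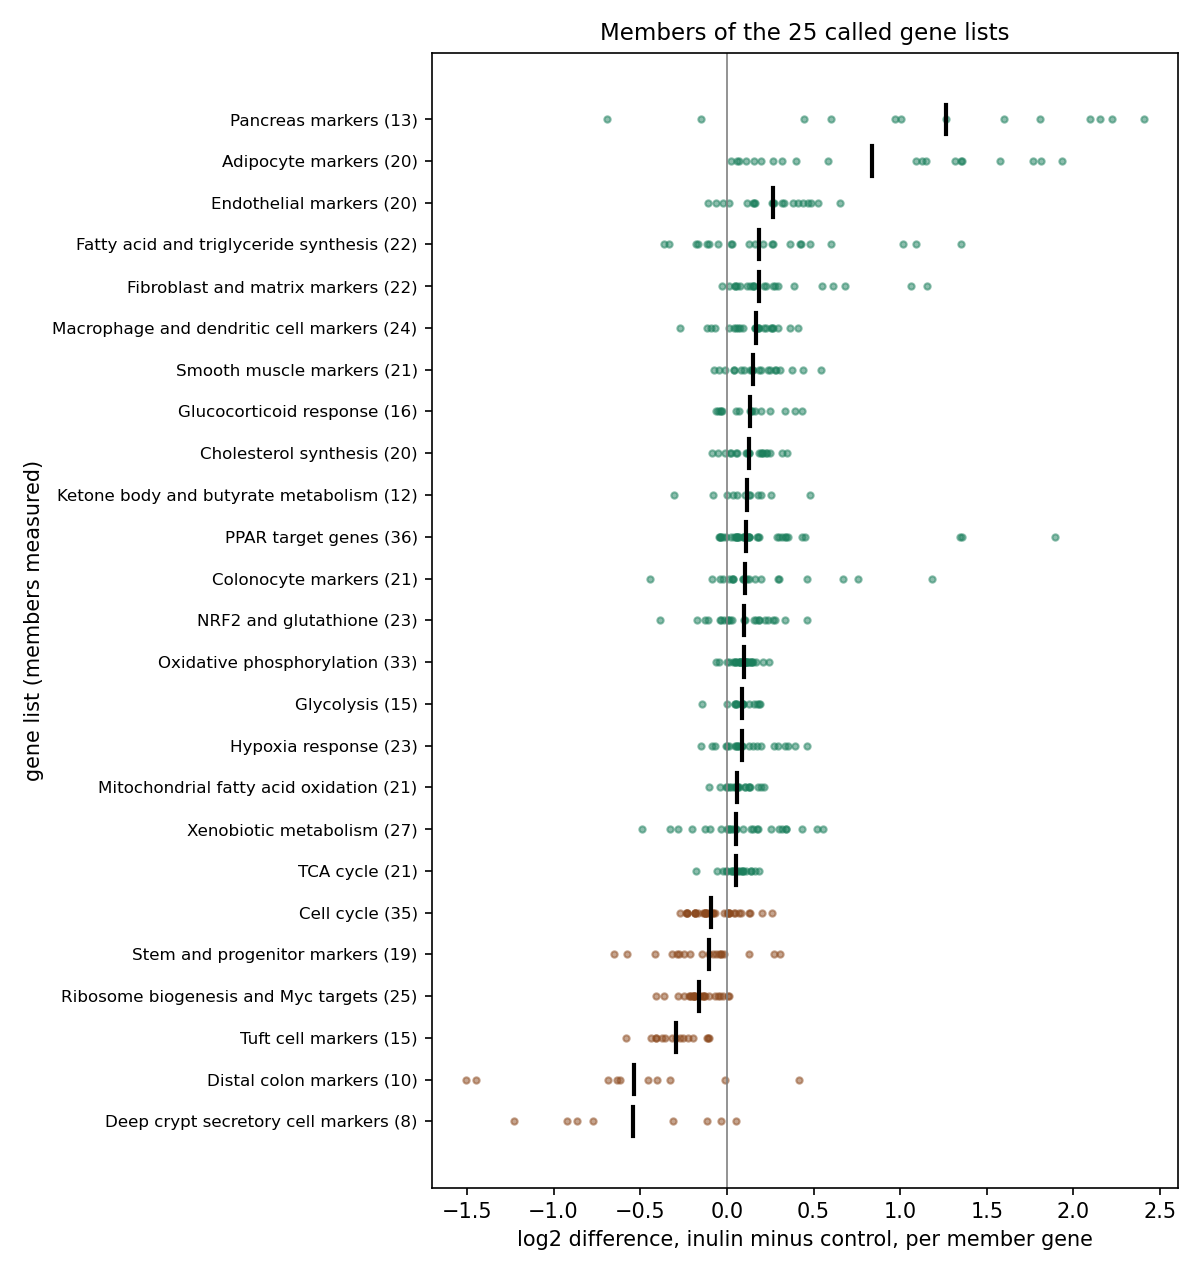
Log2 difference, inulin minus control (horizontal axis), of each measured member (points) of the 25 lists that passed camera at its preset correlation, with the list median as a black bar, green for lists that rose and brown for lists that fell. The 15 tuft cell genes all lie below 0, and fat cell and pancreas markers spread widest to the right.

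Markers of other tissue differed between the diets too. Adipocyte markers rose (adjusted p 6.1e-10; adjusted p = 0.39 with an estimated correlation), 20 of 20 higher with a mean difference of 0.83, and 12 passed adjusted over the list alone, including the fat cell genes Fabp4 (3.82-fold) and Adipoq (2.99-fold) besides Cidec and Pck1 (1.24-fold). Counted on the 17 markers in no other list, inulin mice 5, 4 and 2 had means of 8.24, 8.00 and 7.59, inulin 1, 3 and 6 had 6.89, 6.93 and 6.64, and controls lay between 6.47 and 6.92. Pancreas markers rose (adjusted p 0.0033; adjusted p = 0.56 with an estimated correlation), with the zymogen gene Ctrb1 at 5.30-fold and Clps at -0.69, and the mean was 9.84 in inulin 3 against 5.23 to 7.44 in the other mice. Fibroblast (Dcn 2.09-fold, Postn 1.60-fold), endothelial (Kdr 1.40-fold, Esam 1.30-fold) and smooth muscle markers (Acta2 1.46-fold, Tagln 1.30-fold) rose with adjusted p of 9.3e-06, 5.6e-05 and 0.00031, and adjusted p = 0.39, 0.47 and 0.32 with an estimated correlation. Kdr was at 3.61 in control, below the lower quartile of the arrays. Macrophage markers (Ms4a7 1.29-fold, Cd163 1.19-fold, both past the threshold over the list alone) rose with adjusted p 0.013 (adjusted p = 0.51 with an estimated correlation). Cd163, at 3.53 in control and 3.78 under inulin, was near or below the lower quartile of the arrays. With fat and pancreas covariates the fibroblast, endothelial and macrophage means turned to -0.01, -0.03 and -0.11, smooth muscle did not pass (adjusted p 0.40), and without inulin 3, 4 and 5 the pancreas mean turned to -0.02 and macrophage markers did not pass (adjusted p 0.53). Over all genes 0 members of these 6 lists passed.

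Genes that mark the distal end of the colon fell (adjusted p 0.00010; adjusted p = 0.37 with an estimated correlation). The homeobox genes Hoxd10 and Hoxd11 differed by -1.50 ± 0.26 (SE) and -1.45 ± 0.26 (SE), each 0.055 after adjustment over all genes, and 4 of 10 members, with Hoxd12 and the claudin gene Cldn8, fell adjusted over the list alone while 0 passed over all genes. Hoxb13 differed by -0.62 ± 0.28 (SE), and its mean with Hoxa13 was 7.67 in inulin 4, 8.52 and 8.34 in inulin 1 and 2, and 8.99 to 9.38 in the other inulin mice, against 8.79 to 9.41 in control. Of the 17 genes, 4 passed with fat and pancreas covariates (Gnat3, Itgb8, Itln1 and Reg3g), 7 with the Hox covariate (Reg3g, Mal, S100g, Fa2h, Gnat3, Ttyh1 and Cspg4), and 11 without inulin 3, 4 and 5. All 17 kept their direction in these fits, though leaving out mice could not turn it because the groups did not overlap.

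**Figure D4:**
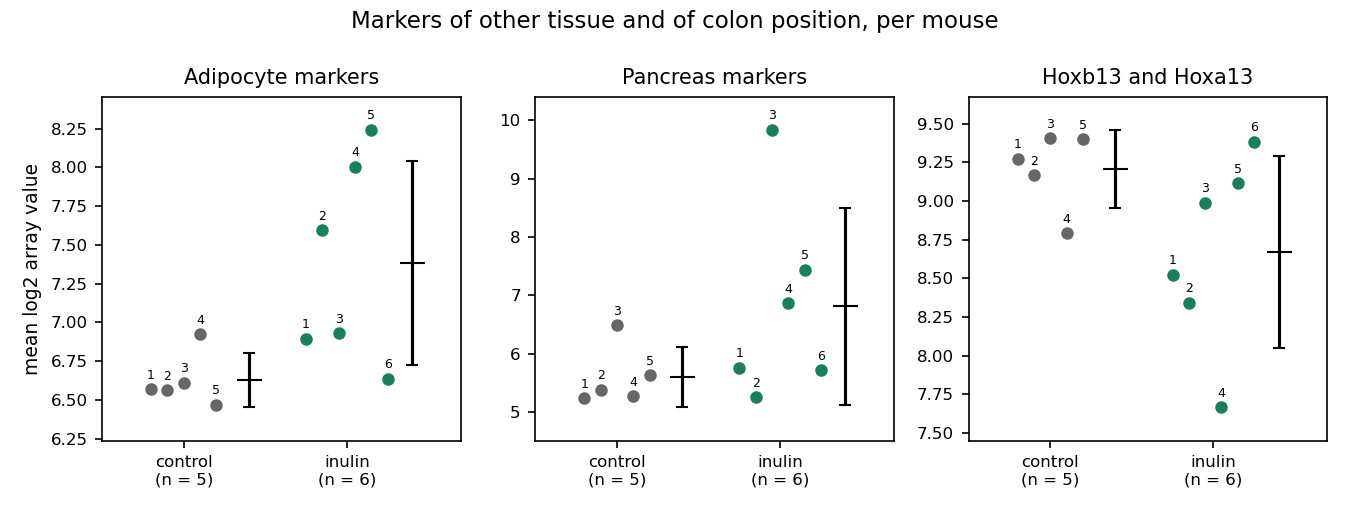
Mean log2 array value (vertical axis) per mouse, numbered, of 17 adipocyte markers, 13 pancreas markers, and Hoxb13 with Hoxa13, in control (grey, n = 5) and inulin (green, n = 6), with mean and SD as black bars. Inulin 4 and 5 are highest for fat (8.00 and 8.24), inulin 3 for pancreas (9.84), and inulin 4 lowest for the Hox genes (7.67).

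The remaining 19 lists did not pass. Antimicrobial and barrier defence genes (adjusted p 0.17) went both ways: over all genes Reg3g and Reg3b rose and Itln1 fell, and adjusted over the list alone 6 rose, including the nitric oxide synthase gene Nos2 (1.98-fold) and Reg3a (1.64-fold, from 3.10 in control, below the lower quartile of the arrays), and 4 fell, including Ang4 and Retnlb. In fry's test for change in either direction the adjusted p of this list was 4.2e-07, and 14 of the 44 lists passed that test. Calcium and mineral genes (adjusted p 0.20) had S100g past the threshold over all genes, and 4 fell adjusted over the list alone: S100g, the calcium channel gene Trpv6 (-0.72 ± 0.17 SE), the magnesium channel gene Trpm6 (-0.51) and the iron importer gene Slc11a2 (-0.36). Their mean difference was -0.13 while their median was 0.0060. Enteroendocrine markers (adjusted p 0.28, mean 0.09, median -0.01) held Cck, past the threshold over all genes, and 2 over the list alone, Cck and Nts (1.77-fold). Granulocyte and mast cell markers (adjusted p 0.088) held the mast cell protease genes Mcpt2 (-1.04 ± 0.21 SE) and Mcpt1 (-0.69 ± 0.18 SE), both past the threshold over the list alone. Under inulin Mcpt2 was at 3.88, near the lower quartile of the arrays.

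Abcg2 and the sodium exchanger gene Slc9a3 (1.40-fold) rose over the list alone among short-chain fatty acid transport and sensing genes (adjusted p 0.18), and Slc9a3 rose and the potassium channel subunit gene Kcne3 (-0.31) fell among ion and water transport genes (adjusted p 0.92). The mucin glycosyltransferase gene Gcnt3 (1.36-fold) rose among goblet cell markers (adjusted p 0.33), the bile acid carrier Slc10a2 (1.61-fold) and Fabp2 among small intestine markers (adjusted p 0.14), and Myc fell among immediate early genes (adjusted p 0.37), each over the list alone and not over all genes. No member passed among unfolded protein response (adjusted p 0.18), B cell (0.31; Ighm 1.54-fold, Jchain 1.56-fold), blood cell (0.36; Pf4 0.20, Gp9 0.10), interferon (0.62), T cell (0.74; Cxcr6 -0.18, Gzmb 0.34), inflammation (0.85), MHC class II (0.93), enteric nerve (0.94; Chat -0.29, Nos1 0.16), circadian (0.97) and tight junction genes (0.98). Mean and median differed in sign for inflammation (0.0035 and -0.0012), enteric nerve (-0.0039 and 0.00041) and tight junction genes (-0.01 and 0.0070), and camera gave circadian genes a downward sign with a mean of 0.0093.

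With an estimated correlation 0 of the 44 lists passed camera, and 5 had an unadjusted p under 0.05, so each list call above rests on the preset correlation of 0.01. Of the 850 measured genes of the lists, 5 passed in limma over all genes (Reg3g, Reg3b, Itln1, S100g and Cck) and 204 had an unadjusted p under 0.05. By fry 2 lists passed, oxidative phosphorylation and deep crypt secretory cells (both adjusted p 0.037), and by exact permutation of the list means 2 passed, colonocyte and calcium genes (both adjusted p 0.048), with 15 at an unadjusted p under 0.05.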

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

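The tests of the 4 PPAR genes against fat and position were chosen after the result was seen, as were all fits with fat, pancreas or Hox covariates and without inulin 3, 4 and 5. Within each diet, 274 sets of values (137 genes or list means in each of the 2 diets) were searched for a mouse far from the others by Dixon's test, and 29 stood out, where chance gives about 1 in 20. Inulin 5 stood apart most often. It was highest among the inulin mice for Itln1 (5.98), Itgb8 (5.18), Pf4 (5.29) and the list means of B and plasma cells (7.10, others 4.99 to 5.59), MHC class II (8.72), macrophages (5.53), antimicrobial genes (8.66) and glycolysis (10.18), and lowest for Ndufs8 (10.42), Myc (7.83), Ascl2 (5.08), stem cell markers (6.84) and ketone body genes (8.51). Inulin 4 was highest for Pparg (10.82) and lowest for Slc16a1 (10.38), and inulin 6 was lowest for goblet cell markers (10.34). Control 4 was highest among controls for Mal (8.10), Nqo1 (8.02) and Slc10a2 (9.67), and lowest for Slc16a1 (10.72) and Slc5a8 (11.39). Control 5 was lowest for Ttyh1 (5.35) and Postn (5.68) and highest for blood cell markers (4.35), control 3 was highest for Acta2 (7.13) and small intestine markers (6.41), control 2 was lowest for Pfkl (9.31) and NRF2 genes (8.91), and control 1 was lowest for hypoxia genes (8.54).

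The 17 genes past the threshold were first set against chance: 2 of 100 splits drawn from the 462 possible, the real one included, gave as many genes. A count this high was rare among the drawn splits, which does not exclude chance. The other of these splits called 139 genes, several times the real 17, which points to a structure of the samples other than diet. It parts control 4 and inulin 1, 2, 4 and 5, the 5 mice highest on the first principal component, from the rest, and these 5 had a mean of 7.53 for fat markers against 6.63 and of 8.49 for Hoxb13 and Hoxa13 against 9.27. Fat and pancreas tissue as the whole source for the 17 genes as a set is argued against by a median ratio of corrected to uncorrected change of 0.918 (0.852 to 1.03 leaving out each mouse). With the Hox covariate the ratio was 0.961 (0.900 to 0.967), and 0.917 (0.824 to 1.02) for Hoxd10, Hoxd11 and Hoxd12, distal markers themselves. Inulin 3 and 5 had Hoxd10 at 5.39 and 5.14 (controls 6.54 to 7.97) but Hoxb13 with Hoxa13 at 8.99 and 9.11, within controls. The covariate may thus miss part of position, so these ratios cannot decide on it. With the fat and pancreas covariates 13 of the 17 calls ended, with a larger standard error in 13 and a smaller change in 10, and with the Hox covariate 10 ended, with a larger standard error in 7 and a smaller change in 9, Cck, Lpo and Cwh43 among them with a smaller change alone (median change 0.60 before, 0.63 and 0.54 after; median SE 0.088 before, 0.10 and 0.098 after). An effect of diet remains a hypothesis, and a part played by position, or by fat in single genes, stays open.

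The higher PPAR target list may come in part from fat tissue in the scrapings. With the fat covariate its mean difference was 0.581 of the uncorrected one, with a range from -0.084 to 0.963 when each mouse was left out. The markers of this covariate include Pparg itself, so it could remove an effect of diet through PPARγ along with fat. For this reason, and with so few mice, fat and an effect of diet cannot be told apart for the list as a whole. Angptl4, Pdk4, Acot2 and Ehhadh were named because inulin 1 and 2 were highest. With the fat covariate the excess of these mice in the mean of the 4 genes was 0.998 of the uncorrected one (0.958 to 1.03 leaving out each mouse). That ratio decides little, because the genes and mice were chosen for high values and the fit gave these mice a term of their own. The values per mouse argue against fat as the whole source. Inulin 1 had fat markers at 6.89, within the control range of 6.47 to 6.92, and inulin 2 at 7.59. Inulin 5 and 4, with most fat, had Angptl4 at 6.59 and 6.75, within that of controls, and the mean of the 4 genes at 8.14 and 8.62. Of the 20 adipocyte markers 3 stand in other lists and 13 lay above the median of every array in control colon too, while Fabp4 went from 6.23 to 8.17 and Adipoq from 5.01 to 6.59. Inulin 1 and 2 also had Hoxb13 and Hoxa13 below every control (8.52 and 8.34), and the Angptl4 difference between the diets went from 0.33 to 0.02 with the Hox covariate. But the excess of these mice in the 4 genes was 0.925 of the uncorrected one with it (0.903 to 1.08 leaving out each mouse), a ratio with the same weakness as for fat. Inulin 4, lowest at 7.67, had the mean of the 4 genes at 8.62, little above controls (8.18 to 8.47) against 9.76 and 9.58 in inulin 1 and 2. Hoxb13 and Hoxa13 may miss part of position, so these values do not decide on it. The timing of the last meal, on which the labels differ, was not tested.

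The lower tuft cell and deep crypt secretory lists were set against dilution of the epithelium by other cells. Dilution would lower goblet cell markers too, though bright members near the top of the arrays, such as Muc2 at 13.1, may show it less. Goblet members went both ways, 8 higher and 9 lower. The tuft mean fell against the goblet mean by 0.26 (exact permutation p 0.022, two-sided) and the deep crypt secretory mean by 0.50 (exact permutation p 0.013). In the latter test Tff3, Agr2 and Spink4, held by both lists, were left out of the goblet mean. For both lists this argues against dilution as the whole source. Another position along the colon, as far as Hoxb13 and Hoxa13 follow it, is argued against for tuft cells. Their difference was 1.29 times as large with the Hox covariate (1.16 to 1.42 leaving out each mouse). For deep crypt secretory cells the ratio was 0.870 with a range from 0.646 to 0.995, so position and diet cannot be told apart there because single mice moved the ratio. For the tuft list an effect of inulin is a hypothesis, found and tested on the same data, and a part played by position stays open.

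The 25 called lists have a caveat of their own: 1 of 100 drawn splits, the real one, gave as many, yet the other splits called a median of 14 and up to 24 lists. So narrow a margin does not exclude chance for the count, and a single list call at the preset correlation carries little weight.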

How the results depend on the processing

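The covariate fits, the fit without inulin 3, 4 and 5, and the exact permutation of list means were chosen after seeing the data. All 17 genes kept their direction in all 204 values under 12 alternatives (154 past the threshold) and in all 187 with each mouse left out (122 past it). The groups did not overlap for any of the 17, so leaving out mice could not turn a direction. Alternatives that change only the variance or the genes tested reuse the same difference. In all such fits the kept direction was fixed in advance. The count of 17 genes (10 higher, 7 lower) became 42 (23 and 19) with an intensity trend, 245 (108 and 137) with array weights, which gave inulin 5 the lowest weight, 47 (24 and 23) without dim probe sets, where fewer genes were tested, 62 (44 and 18) with median centring, 6 (4 and 2) at 0.01, 130 (68 and 62) at 0.1, 7 (5 and 2) over all probe sets, and 0 (0 and 0) with the unmoderated unequal-variance test, where 2446 genes had an unadjusted p under 0.05, against 2547 in limma. It was 16 (3 and 13) with fat and pancreas covariates, 33 (13 and 20) without inulin 3, 4 and 5, and 22 (8 and 14) with the Hox covariate, and between 7 and 98 (5 to 42 higher, 2 to 56 lower) with each mouse left out; other than by their construction, the cause was not tested. Replicate numbers are shared between the diets, and the values show no clear pairing of the mice: 2 of 5 pairs had a correlation above 0.1 (-0.10 to 0.22), and 2 controls matched their own number best. A shared block is not excluded by this. With the replicate number as a block 95 genes (54 and 41) and 20 lists passed and Slc16a1 was at -0.018, but the block also takes inulin 6, which has no partner, out of the comparison: leaving out inulin 6 alone gave 50 genes (28 and 22), 20 lists and the same Slc16a1 difference. Taking out inulin 6 therefore does not account for the whole rise to 95 genes. Angptl4 stayed short of the threshold everywhere (0.02 with the Hox covariate to 0.79 without the 3 mice, and 0.10 to 0.51 leaving out each mouse). Small differences turned sign for Slc16a1 (-0.011 with quantile normalisation), Hcar2 (-0.066, -0.0080 and -0.019 with the fat and pancreas covariates, without the 3 mice and with the Hox covariate), Ffar3 (0.014 without the 3 mice), Cpt1a (-0.047) and Slc26a3 (0.18, both with the Hox covariate), and when a mouse was left out for Cpt1a (-0.0020 to 0.044), Ffar3 (-0.13 to 0.055), Hcar2 (-0.0091 to 0.049), Slc16a1 (-0.018 to 0.10) and Slc26a3 (-0.11 to 0.053). The 25 lists became 0 with an estimated correlation (5 at an unadjusted p under 0.05), 2 by fry and 2 by exact permutation, and 18 to 25 otherwise (20 to 25 leaving out each mouse), though not always the lists called before: of these calls, 11 of 23 were kept with fat and pancreas covariates (8 lost, 4 turned) and 17 of 24 with the Hox covariate (6 lost, 1 turned), lists that gave the covariates aside, 18 of 25 without the 3 mice (6 lost, 1 turned) and 20 of 25 with the block and without inulin 6, where ketone body, cholesterol, TCA cycle, NRF2 and glucocorticoid lists did not pass. In all, 14 of the 25 calls were kept whichever mouse was left out. Calls ended for cell cycle without control 1, 3 or 4 or inulin 2, 4 or 5, for TCA cycle without control 1 or 2 or inulin 1 or 6, for glucocorticoid genes without control 4 or 5 or inulin 5 or 6, for NRF2 genes without control 2 or inulin 1 or 6, for cholesterol synthesis without control 2 or inulin 3 or 6, for xenobiotic genes without control 1 or inulin 4, for fatty acid oxidation without inulin 1 or 2, for glycolysis, hypoxia and macrophage lists without inulin 5, and for ketone body genes without inulin 6. Array weights ended the calls of cholesterol, cell cycle, glucocorticoid and macrophage lists, quantile normalisation those of ketone body, TCA cycle, cell cycle and NRF2 lists, leaving out dim probe sets those of cell cycle and macrophages, the mean of probe sets that of cell cycle, and ranks that of NRF2 genes. List means turned sign with fat and pancreas covariates for cell cycle (0.039), macrophage (-0.11), fibroblast (-0.011) and endothelial markers (-0.029), without the 3 mice for pancreas markers (-0.023) and with the Hox covariate for xenobiotic genes (-0.037). Signal limits what low genes can show: Hcar2, Cd163, the control values of Reg3a and Kdr, and the inulin values of Itln1 and Mcpt2 lie near or below the lower quartile of the arrays.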

Other observations

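No test in this part was chosen after its result was seen, except that on members above the lower quartile, and the weight given to the low level of the list was decided after its result was seen. Several genes named here were chosen after their values were seen. Itln1 fell by 2.21 on the log2 scale, and Retnlb (-0.92 ± 0.28 SE), Ang4 (-1.23 ± 0.35 SE), the mast cell protease gene Mcpt2 (-1.04 ± 0.21 SE) and Mcpt1 (-0.69 ± 0.18 SE), none past the threshold over all genes, were lower along with 15 of 15 tuft cell genes, while Reg3g rose 7.10-fold and Reg3b 4.93-fold and the oxidase gene Duox2 differed by 0.45 ± 0.18 (SE). The inulin values of Itln1 and Mcpt2 lay near the lower quartile of the arrays.

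A hypothesis is that a weaker type 2 signal underlies the lower genes. It was tested on 17 other cytokine, receptor and response genes of type 2 immunity, whose mean would be lower under inulin if so. The mean was instead higher by 0.075 (13 of 17 genes higher, exact permutation p 0.0498, two-sided), opposite to the prediction, and no gene passed (smallest limma adjusted p 0.35). The median control level of the list was 3.56, under the lower quartile of every array, so genes at that level cannot exclude the hypothesis, and for the 7 above it the mean was higher by 0.13 with an exact permutation p of 0.17. The data give the hypothesis no support and do not settle it.

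The 14338 probe sets with several symbols or none, tested on their own in limma, gave 0 past the threshold and 1219 at an unadjusted p under 0.05.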
